A study of Homo sapiens with 60 samples.

How the data were processed

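The measurement is messenger RNA sequencing of A549 cells 24 h after treatment, in 60 libraries of 25 groups: a vehicle group of 3 and 8 extracts at 20, 100 and 500 µg/mL. Of the groups, 16 have 3 libraries, 3 have 2 and 6 have 1. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to the GRCh38 genome and quantified per gene with RSEM 1.3.3. The annotation release and the strand setting are not given in the sources used here. The authors deposited expected counts per gene, a table of 60675 gene identifiers in 270 columns. The 60 columns of this series were used and the other 210 were not used here. Of the values above 0, 76.6% were whole numbers within 1e-09, and all were rounded before fitting. The vehicle labels give 0.1% DMSO and the design text 2%, the library labels give the 3 doses for every extract while the design text gives lower, IC20-based doses for extracts whose IC20 is under 500 µg/mL, and the positive control the design text names is not among these libraries.

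Gene symbols came from the deposited identifiers matched to the gene name tables and to GENCODE 29, which also gave the GRCh38 positions. Totals per library were 18602484 to 29764358 counts, and 21744 to 28101 genes had counts above 0. A filter on low counts (filterByExpr of edgeR 4.0.16, R 4.3.3) left 17764 genes. Libraries were scaled by TMM, and a model with 1 mean per group was fitted to all 60 libraries (estimateDisp and glmQLFit), giving 35 residual degrees of freedom and a common biological coefficient of variation of 5.59%. Over 51 replicate pairs the chi-square per degree of freedom ran from 2.72 to 40.3, so no pair lay within sampling noise. RLE size factors moved no library by more than 0.00674 log2 against TMM.

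Comparisons, tests and gene lists were fixed before the data were examined, except the tests of a difference between 2 extracts in their dose change, the comparison of the mean low dose with the vehicle with its 4 tests (length and GC correction, thinning, growth with dose, set codes), the 3 tests of the Poria library and a replicate block within set codes, which were added later. There were 18 comparisons of a dose with the vehicle, 6 of high with low dose and 3 of extracts within a set of sample codes, each tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. SEs are the log2 change divided by the square root of F. They understate the uncertainty where 1 group has few counts, as for CYP1A1 at low dose, in the vehicle and with Ginseng. Differences between extracts in their high against low change were tested as interactions in the same model. In all 34 gene lists (592 entries, 1 unmatched) were written by hand from textbook knowledge, covering xenobiotic and lipid metabolism, stress and signalling responses, cell cycle, secreted and structural genes and markers of other cell types. Lists with at least 5 tested genes, 32 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Overlaps between extracts were set against hypergeometric expectations.

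The genes named in each comparison were chosen by a fixed rule. For high dose against vehicle these were the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in either group and an approved symbol, and for the other high-dose comparisons the 5 largest each way. Added to them were the 4 members with the smallest adjusted p of each list with camera adjusted p under 0.05, and 10 fixed genes (CYP1A1, CYP1B1, TIPARP, HMOX1, CDKN1A, HMGCS1, DDIT3, ASNS, CXCL8 and MKI67) in every comparison. Only part of the genes the rule names are printed. For Angelicae and Paeoniae, with no replicates, genes had at least 10 CPM, a change in the same direction that grew over the doses and a high-dose value outside the vehicle range, and the 5 largest each way were taken, with log2 ratios of CPM plus 1. Their list medians were set against 10000 random lists. KLHL30, FUT1, IL1A, MATN2 and ID1 lie outside the rule and were chosen after their values were seen.

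The fits were tested on simulated data with known changes in 200 genes (17332 genes passed the filter). With 3 libraries against 3 (Glycyrrhizae), 23, 37, 40 and 46 of 50 genes were recovered at 1.25-, 1.5-, 2- and 4-fold, and 11 of 17111 unchanged genes tested were called. With 2 against 2 (Palmul-tang), 15, 34, 36 and 45 were recovered and 3 unchanged genes called, and with no change added (Ginseng) 0 were called. The simulated genes varied independently, with the same dispersion rule in every group. These counts therefore do not cover unequal spread between groups or handling shared by libraries. The alternatives tried were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the compared groups, leaving out each library, a replicate block, an estimated correlation in the list tests, and for the unreplicated extracts another pseudocount (0.1) and no CPM minimum. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.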

Results

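RNA was sequenced from A549 cells, a human lung adenocarcinoma line that grows attached in culture, 24 h after the cells received herbal extracts used in Korean tonic medicine. RNA sequencing counts the transcripts of each gene in a library made from messenger RNA. The 60 libraries fall into 25 groups. A vehicle group (DMSO, n = 3) stands beside 8 extracts at 20, 100 and 500 µg/mL, called low, medium and high here. Water extracts of the multi-herb formulas Sibjeondaebo-tang (n = 3 per dose) and Palmul-tang (n = 2 per dose) were included. The single-herb ethanol extracts were Poria, Atractylodis, Glycyrrhizae (licorice) and Ginseng (n = 3 per dose), and Angelicae and Paeoniae (1 library per dose). Library totals ran from 18602484 to 29764358 counts. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

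The first question was which genes changed between 20 and 500 µg/mL of the same extract, a comparison that does not involve the vehicle libraries. Changes are log2 ± SE unless another unit is given, CPM is a gene's count scaled to the same library total in every library, and 17764 genes were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The number of genes called ran from 37 for Atractylodis to 6568 for Glycyrrhizae.

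The Glycyrrhizae extract gave the largest single-gene change of the 6 extracts tested. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610 on GRCh38), which encodes an enzyme that oxidises polycyclic aromatic compounds and is induced through the aryl hydrocarbon receptor, rose by 8.82 ± 0.16 (215 ± 5.34 against 0.466 ± 0.204 CPM, mean ± SD, n = 3 and 3; edgeR adjusted p = 8.02e-38). Of the genes on the aryl hydrocarbon receptor list, 8 of 11 rose (8 adjusted over the list alone; camera adjusted p = 3.3e-52) and 2 fell. These included CYP1B1 (2.65 ± 0.04), the related enzyme, and TIPARP (2.19 ± 0.05), an ADP-ribosyltransferase that represses the receptor. CYP1A1 had 16, 6 and 16 counts in the low-dose libraries, so its SE understates the uncertainty.

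Genes of the amino acid and stress response driven by the transcription factor ATF4 moved together at high Glycyrrhizae dose: 25 of 27 rose (25 adjusted over the list alone; camera adjusted p = 2.6e-160). ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), asparagine synthetase, rose by 2.82 ± 0.05 (237 ± 12.7 against 33.4 ± 1.21 CPM, mean ± SD). Also higher were PHGDH (2.28 ± 0.04), the first enzyme of serine synthesis, the secreted glycoprotein STC2 (2.57 ± 0.05), the mitochondrial enzyme PCK2 (2.68 ± 0.07) and the stress transcription factor DDIT3 (2.15 ± 0.09). Amino acid transporters followed, where 10 of 12 rose (10 adjusted over the list alone; camera adjusted p = 1.6e-30), among them SLC1A4 (2.30 ± 0.09) and SLC7A5 (1.11 ± 0.05). Among the largest rises of genes at 5 CPM or more were ADM2, a peptide hormone of the calcitonin family (4.80 ± 0.20), ULBP1, a ligand of the natural killer cell receptor (4.61 ± 0.29), NIBAN1 (4.12 ± 0.16) and the glutathione-degrading enzyme CHAC1 (3.42 ± 0.12).

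Genes read out by growth-factor signalling through MAP kinases rose as well: 15 of 20 rose (16 adjusted over the list alone; camera adjusted p = 6.39e-15), with ETV4 (1.46 ± 0.06) and DUSP5 (1.47 ± 0.08) higher and 2 genes lower. On the p53 list 11 of 22 rose (11 adjusted over the list alone; camera adjusted p = 6.26e-05), including the secreted factor GDF15 (2.47 ± 0.10) and the cell cycle inhibitor CDKN1A (0.81 ± 0.05), while 2 fell. HMOX1, heme oxygenase, rose by 1.36 ± 0.08 and CXCL8, a neutrophil chemokine, by 0.80 ± 0.15.

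Secreted blood proteins went down at high Glycyrrhizae dose. On the coagulation and complement list 12 of 16 fell (12 adjusted over the list alone; camera adjusted p = 5.08e-10), with the fibrinogen chain FGB (-1.29 ± 0.04) and the plasminogen activator PLAU (-0.96 ± 0.06). Of the hepatocyte markers, several of which A549 cells express at a low level, 4 of 6 fell (5 adjusted over the list alone; camera adjusted p = 2.76e-06), such as APOB (-2.42 ± 0.14) and TF (-1.73 ± 0.12). Glucocorticoid-responsive genes were lower, where 10 of 16 fell (10 adjusted over the list alone; camera adjusted p = 6.33e-08), with SGK1 (-1.04 ± 0.04) and FKBP5 (-0.56 ± 0.03) as examples. Among genes at 5 CPM or more, large falls were in the tight-junction gene CLDN2 (-3.61 ± 0.31), the Nodal antagonist LEFTY1 (-3.34 ± 0.16), the kinase MAPK4 (-3.07 ± 0.12) and the pepsinogen gene PGC (-3.02 ± 0.11). EIF3CL was also called (-3.23 ± 1.12), but its reads are shared with a near-identical copy, and it was not called without high-dose replicate 1 or 2 or low-dose replicate 3 (edgeR adjusted p = 0.0885, 0.0772 and 0.0905).

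In the Glycyrrhizae comparison 3295 genes rose and 3273 fell, of which 478 and 381 changed at least 2-fold. The 8 lists above kept adjusted p under 0.05 with an estimated correlation. The lists below did not. Heat-shock genes fell in 12 of 15 (adjusted p = 0.0836 with an estimated correlation), histone transcripts in 8 of 11 (0.0836), nuclear-encoded respiratory chain genes in 13 of 24 (0.424), G2/M genes in 12 of 24 (0.174) and G1/S genes in 9 of 24 (0.302), and LXR targets rose in 6 of 9 (0.102). The vehicle-referred series for CYP1A1 was 0.56 ± 0.45 at 20, 4.82 ± 0.24 at 100 and 9.38 ± 0.18 at 500 µg/mL, with edgeR adjusted p of 0.4, 2.86e-19 and 2.21e-37. For CYP1B1 the series was 0.33 ± 0.04, 1.13 ± 0.04 and 2.98 ± 0.04, and for ASNS it was 0.08 ± 0.05 (not called), 0.26 ± 0.05 and 2.90 ± 0.05.

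**Figure D1:**
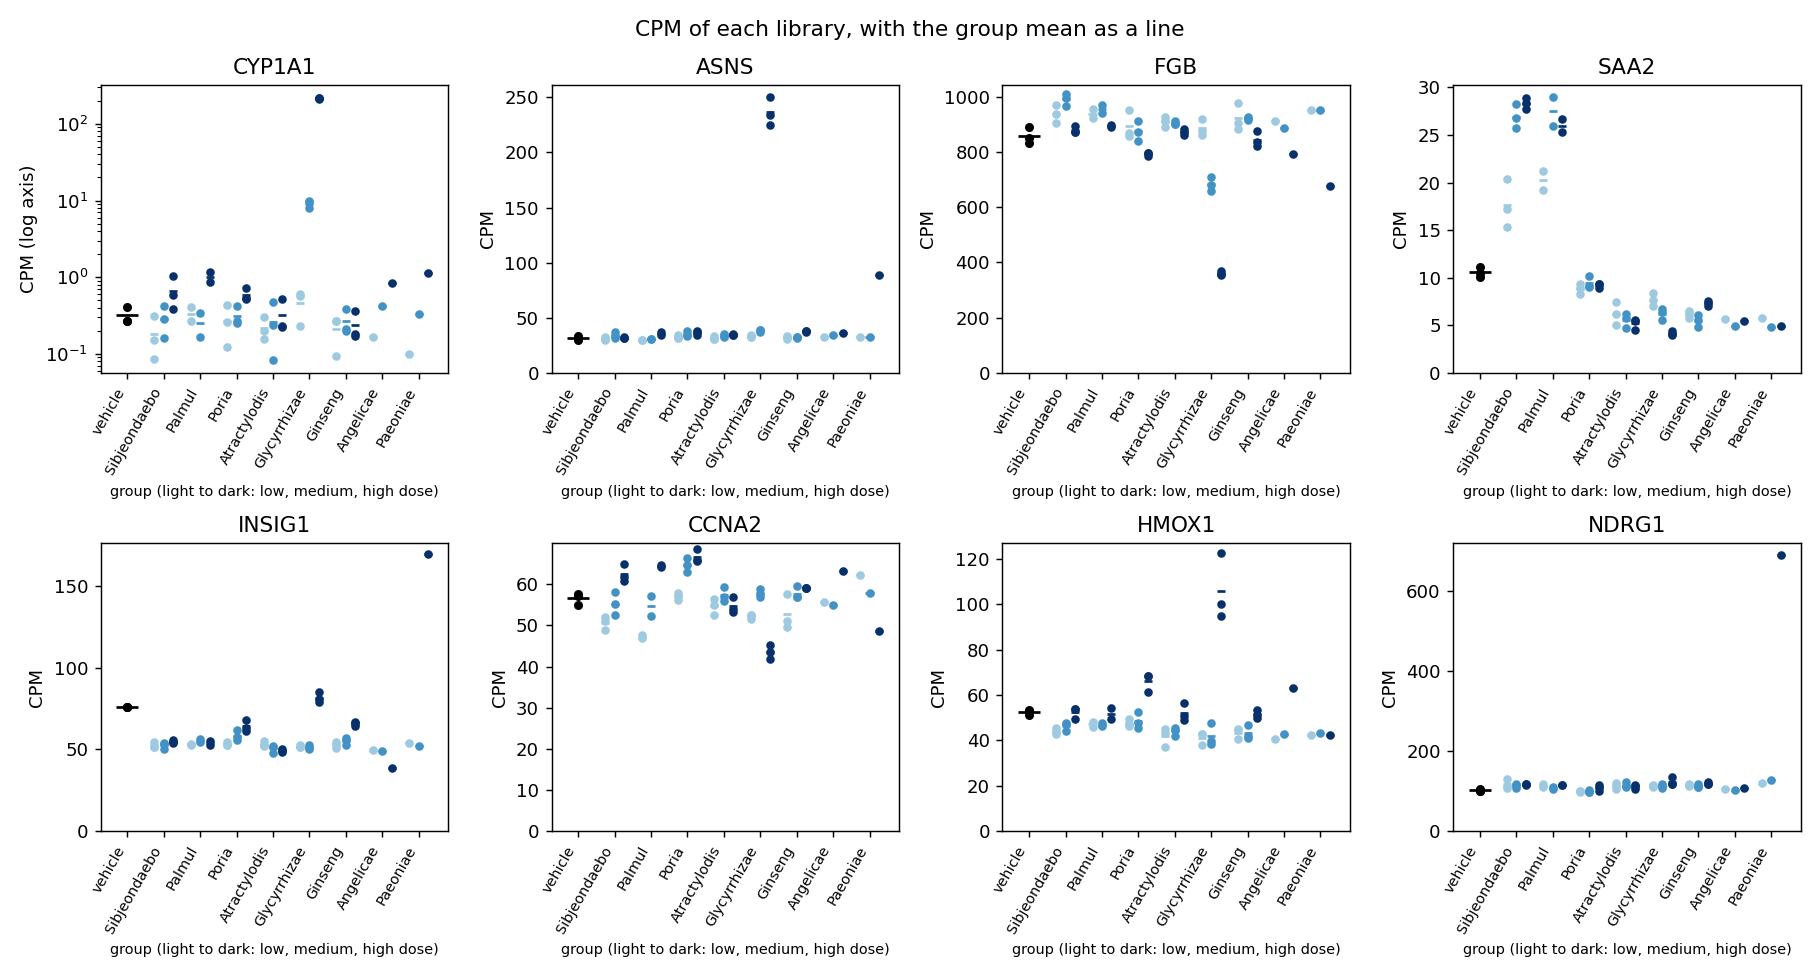
CPM of CYP1A1 (log axis), ASNS, FGB, SAA2, INSIG1, CCNA2, HMOX1 and NDRG1 by group, with 1 point per library, lines at group means and darker points at higher doses. Mean CYP1A1 at high Glycyrrhizae dose was 215 CPM against 0.316 CPM in the vehicle.

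The Sibjeondaebo-tang water extract raised cell cycle and inflammation genes between low and high dose. In the G2/M group 21 of 24 rose (23 adjusted over the list alone; camera adjusted p = 2.48e-54), for example CDC20 (0.36 ± 0.04), an activator of the anaphase-promoting complex, and the kinase AURKB (0.41 ± 0.05). In the G1/S group 18 of 24 rose (21 adjusted over the list alone; camera adjusted p = 3.96e-46), such as RRM2 (0.34 ± 0.04) and TYMS (0.38 ± 0.05), which supply nucleotides for DNA synthesis. On the NF-kB cytokine list 5 of 24 rose (9 adjusted over the list alone; camera adjusted p = 1.63e-05), with the chemokine CXCL8 (0.56 ± 0.13) and SAA2 (ENSG00000134339, chromosome 11, 18239223 to 18248643), an acute-phase protein (0.68 ± 0.09; edgeR adjusted p = 1.17e-06; 28.3 ± 0.589 against 17.6 ± 2.58 CPM, mean ± SD, n = 3 and 3). SAA1 and SAA2 are near-identical, so reads can be shared between them. Without low-dose replicate 2 the CXCL8 call was lost (edgeR adjusted p = 0.0585).

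Of the aryl hydrocarbon receptor targets, 4 of 11 rose (4 adjusted over the list alone; camera adjusted p = 5.74e-05) with Sibjeondaebo-tang, where CYP1B1 (0.35 ± 0.04) and the aldehyde dehydrogenase ALDH3A1 (0.31 ± 0.04) were abundant and CYP1A1 (1.84 ± 0.47) stayed under 1 CPM on average. CYP1A1 was not called without high-dose replicate 1 (edgeR adjusted p = 0.199), low-dose replicate 2 (0.111) or low-dose replicate 3 (0.0892). ATF4 targets rose in 3 of 27 (4 adjusted over the list alone), and mucin and surfactant genes fell in 2 of 11 (4 adjusted over the list alone). Lower genes included FGFBP1 (-0.63 ± 0.08), a carrier of fibroblast growth factors, ANKRD1 (-0.59 ± 0.09) and ID2 (-0.59 ± 0.10), an inhibitor of helix-loop-helix factors. These 6 lists held with an estimated correlation. Heat-shock genes (2 of 15 higher, adjusted p = 0.0725 with an estimated correlation), NRF2 targets (2 of 26 higher and 2 lower, 0.0725), YAP targets (2 of 16 lower, 0.0725), coagulation and complement genes (1 of 16 higher and 1 lower, 0.0687) and PPAR targets (1 of 14 higher, list direction down, 0.0747) did not. In all 417 genes rose and 255 fell. The 672 calls became 323 when only these 6 libraries were fitted, 441 without high-dose replicate 1, 406 without low-dose replicate 2 and 381 without low-dose replicate 3.

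Palmul-tang gave a similar group pattern with 2 libraries per dose. On the G2/M list 23 of 24 rose (24 adjusted over the list alone; camera adjusted p = 2.23e-58), such as the cyclin CCNA2 (0.45 ± 0.05) and topoisomerase TOP2A (0.43 ± 0.06), and on the G1/S list 13 of 24 rose (19 adjusted over the list alone; camera adjusted p = 4.16e-35), such as RRM2 (0.38 ± 0.05) and the helicase subunit MCM4 (0.34 ± 0.04). CYP1B1 rose by 0.48 ± 0.05 (edgeR adjusted p = 2.06e-08; 167 ± 0.984 against 120 ± 4.34 CPM, mean ± SD) and ALDH3A1 by 0.34 ± 0.05, making 2 of 11 aryl hydrocarbon receptor targets (3 adjusted over the list alone). CXCL8 rose by 0.61 ± 0.15, the only called member of 24 NF-kB cytokine genes (8 adjusted over the list alone). That CXCL8 call was lost with no filter on low counts (edgeR adjusted p = 0.123) and without any 1 of the 4 libraries (0.111, 0.158, 0.146 and 0.185 without high-dose replicates 2 and 3 and low-dose replicates 2 and 3). Falls were ID2 (-0.82 ± 0.12), FGFBP1 (-0.78 ± 0.10) and the Wnt antagonist DKK1 (-0.66 ± 0.09). These 4 lists held with an estimated correlation, whereas heat-shock genes (2 of 15 higher; adjusted p = 0.197 with an estimated correlation) and lysosome and autophagy genes (1 of 22 lower; 0.197) did not. The total was 229 genes higher and 141 lower, and the 370 calls became 577 when only these 4 libraries were fitted. Leaving out 1 library gave 169 without high-dose replicate 2, 123 without high-dose replicate 3, 106 without low-dose replicate 2 and 136 without low-dose replicate 3, in fits where the lone library is assumed to vary like the other groups.

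Poria raised cell cycle and lipid synthesis genes between low and high dose. On the G2/M list 15 of 24 rose (23 adjusted over the list alone; camera adjusted p = 5.24e-41), with CDC20 (0.32 ± 0.04) and CCNB1 (0.35 ± 0.06), and on the G1/S list 13 of 24 rose (22 adjusted over the list alone; camera adjusted p = 8.92e-36), with the replication helicase subunits MCM7 (0.28 ± 0.04) and MCM5 (0.36 ± 0.05). Cholesterol synthesis genes were higher: 11 of 25 rose (17 adjusted over the list alone; camera adjusted p = 1.47e-27), including the sterol sensor partner INSIG1 (0.26 ± 0.04) and the sterol reductase DHCR7 (0.31 ± 0.05). Fatty acid synthesis genes rose in 4 of 13 (4 adjusted over the list alone), with the desaturase SCD (0.27 ± 0.04). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) rose by 0.47 ± 0.08 (edgeR adjusted p = 0.00015; 66.2 ± 4.02 against 47.6 ± 1.5 CPM, mean ± SD, n = 3 and 3), 1 of 5 NRF2 targets of 26 that rose (9 adjusted over the list alone).

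ATF4 targets rose in 6 of 27 with Poria (11 adjusted over the list alone), amino acid transporters in 2 of 12 (5), aryl hydrocarbon receptor targets in 3 of 11 (4), hypoxia and glycolysis genes in 2 of 22 (4) and heat-shock genes in 1 of 15 (5). Coagulation and complement genes fell in 5 of 16 (8 adjusted over the list alone), for example FGG (-0.29 ± 0.06), and the drug-metabolising enzyme CYP3A5 (-0.44 ± 0.07) fell, 1 of 7 targets of the xenobiotic receptors PXR and CAR. All 12 of these lists held with an estimated correlation. Endoplasmic reticulum chaperones (none of 18 called, adjusted p = 0.121 with an estimated correlation) and mucin and surfactant genes (none of 11 called, 0.0983) did not. In all 189 genes rose and 86 fell. The 275 calls became 123 when only these 6 libraries were fitted, 144 without high-dose replicate 1, 167 without high-dose replicate 3 and 163 without low-dose replicate 1. Low-dose replicate 3 held 3495 genes seen in at most 3 other libraries, at a mean of 1.43 counts, and the count without it was 186.

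The Ginseng extract raised cholesterol synthesis genes between low and high dose: 17 of 25 rose (21 adjusted over the list alone; camera adjusted p = 5.83e-52). The prenyl diphosphate synthase FDPS (ENSG00000160752, chromosome 1, 155308748 to 155320666) rose by 0.33 ± 0.04 (edgeR adjusted p = 6.06e-07; 154 ± 1.77 against 122 ± 2.42 CPM, mean ± SD, n = 3 and 3), SQLE (0.32 ± 0.04), INSIG1 (0.31 ± 0.04) and ACAT2 (0.36 ± 0.05) rose, and the fatty acid desaturase SCD (0.19 ± 0.04) was 1 of 2 called among 13 fatty acid synthesis genes (4 adjusted over the list alone). The cholesterol exporter ABCA1 (-0.52 ± 0.09) fell, 1 of 9 LXR targets. Secreted liver-type proteins fell, where coagulation and complement genes were lower in 5 of 16 and higher in 1 (11 and 1 adjusted over the list alone), with C5 (-0.34 ± 0.05) and FGA (-0.25 ± 0.04). Hepatocyte markers were lower in 2 of 6 (4 adjusted over the list alone), with the hemoglobin-binding protein HP (-0.72 ± 0.13).

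G2/M genes rose in 4 of 24 with Ginseng (16 adjusted over the list alone), ATF4 targets in 4 of 27 (11), NF-kB cytokine genes in 3 of 24 (8) and MAP kinase output genes in 2 of 20 (3). Examples are STC2 (0.32 ± 0.06) and NFKB2 (0.35 ± 0.06). No G1/S gene was called over all genes by edgeR (8 of 24 adjusted over the list alone), and 1 of 7 PXR and CAR targets fell. The basement-membrane gene NID1 (0.60 ± 0.09) and the glycolytic enzyme ALDOC (0.60 ± 0.10) rose, and LEFTY1 (-0.75 ± 0.12) and the kininogen gene KNG1 (-0.71 ± 0.10) fell. These 11 lists held with an estimated correlation, but hypoxia and glycolysis (2 of 22 higher, adjusted p = 0.072 with an estimated correlation), TGF-beta response (1 of 19 higher, 0.067), mucin and surfactant (1 of 11 lower, 0.0695) and amino acid transport (none of 12 called, 0.182) did not. The total was 98 genes higher and 116 lower. The 214 calls became 21 when only these 6 libraries were fitted, 92 without high-dose replicate 1, 138 without high-dose replicate 3 and 117 without low-dose replicate 2. In the fit of only 6 libraries the genes INSIG1, SCD, ABCA1, FGA, HP, STC2, NFKB2 and LEFTY1 were no longer called (edgeR adjusted p from 0.0589 for INSIG1 to 0.385 for SCD), and SCD was not called with no filter on low counts (0.095).

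Atractylodis changed few genes between doses, 20 higher and 17 lower. The iron carrier TF (0.57 ± 0.10) and the lipase inhibitor ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374373; 0.52 ± 0.07, edgeR adjusted p = 5.83e-05; 62.8 ± 1.14 against 43.8 ± 4.68 CPM, mean ± SD, n = 3 and 3) rose. The apolipoprotein APOB (-0.68 ± 0.12), the chemokine CXCL1 (-0.63 ± 0.11), PDZK1IP1 (-0.46 ± 0.08) and the potassium channel KCNJ16 (-0.42 ± 0.06) fell, where CXCL1 was not called without high-dose replicate 2 (edgeR adjusted p = 0.0531). As a list, hypoxia and glycolysis genes moved up (median 0.15; none of 22 called over all genes, 10 adjusted over the list alone, camera adjusted p = 4.95e-13) and cholesterol synthesis genes moved down (median -0.07; none of 25 called, 5 lower adjusted over the list alone, camera adjusted p = 1.01e-06).

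Further Atractylodis lists that held with an estimated correlation, as both of those did, were ATF4 targets (2 of 27 higher), NRF2 targets (1 of 26 higher), PPAR targets (1 of 14 higher), G1/S genes (none of 24 called), NF-kB cytokine genes (1 of 24 lower) and glucocorticoid targets (1 of 16 lower and 1 higher). Transcripts encoded by mitochondrial DNA had a median of -0.30 at high against low dose, with none of 13 called and adjusted p = 0.267 with an estimated correlation. Other lists lost with it were MAP kinase output (0.127), coagulation and complement (0.127), endoplasmic reticulum chaperones (0.164), amino acid transport (0.174), TGF-beta response (0.15), G2/M (0.201) and mucin and surfactant (0.163). The 37 calls became 21 when only these 6 libraries were fitted, 67 with DESeq2 and 209 with no filter on low counts. They became 22 without high-dose replicate 1, 13 without high-dose replicate 2 and 23 without low-dose replicate 2.

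**Figure D2:**
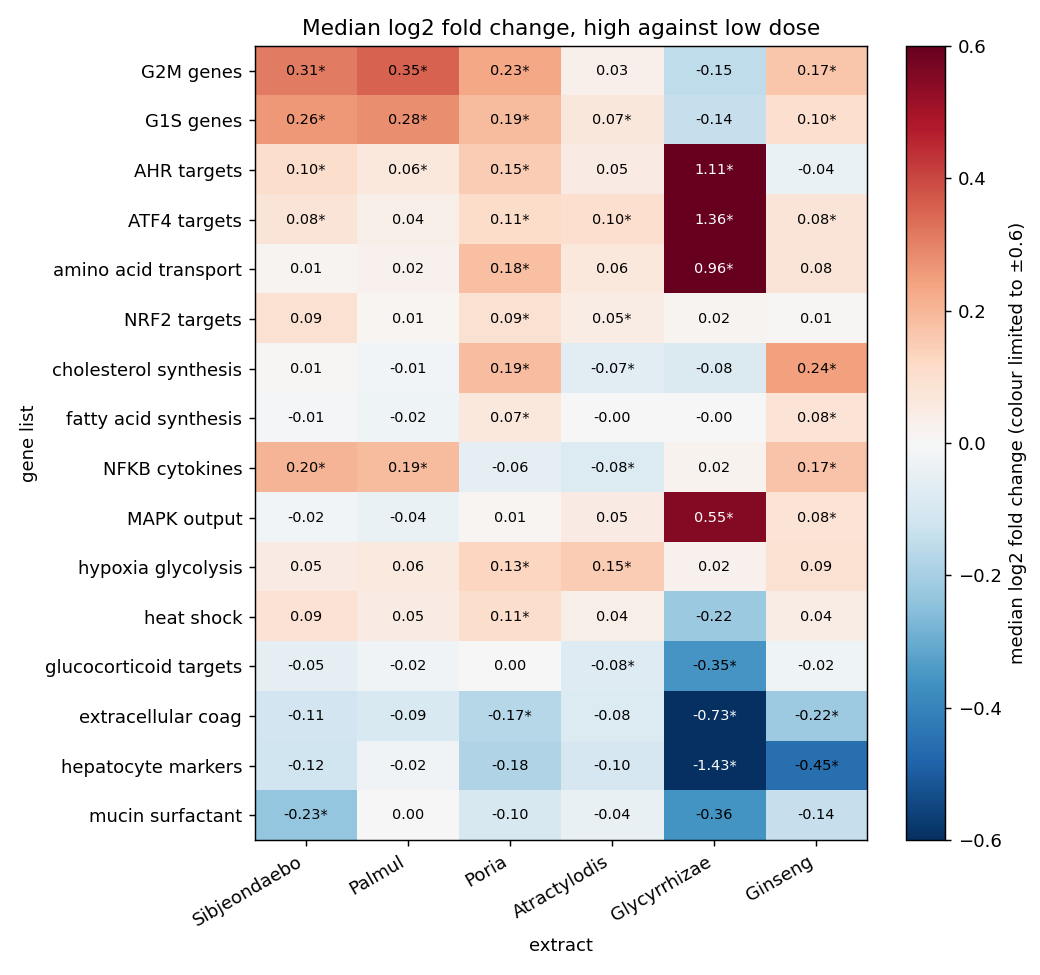
Median log2 change of high against low dose for 16 gene lists (vertical axis) in 6 extracts (horizontal axis), where colour stops at 0.6 and a star marks adjusted p under 0.05 with the preset and with the estimated correlation. The G2/M median was 0.31 for Sibjeondaebo-tang, 0.35 for Palmul-tang and -0.15 for Glycyrrhizae.

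Genes that changed with dose were shared between most pairs of extracts. Sibjeondaebo-tang and Palmul-tang had 146 genes higher in both, against 5.38 for unrelated lists of the same sizes, 65 lower in both against 2.02, and 0 called in opposite directions. Sibjeondaebo-tang and Poria shared 117 higher genes (4.44 by chance) and Palmul-tang and Poria 84 (2.44). Poria and Ginseng shared 39 higher (1.04) and 24 lower genes (0.562). Glycyrrhizae and Ginseng shared 50 higher (18.2) and 99 lower genes (21.4), with 32 called in opposite directions. Overlap with the Glycyrrhizae rises was weaker: Sibjeondaebo-tang shared 103 higher genes with it (77.3 by chance) and had 147 called in opposite directions, Palmul-tang 51 (42.5; Fisher adjusted p = 0.151) and 92, and Poria 61 (35.1) and 63. The lower genes overlapped more, with 167 shared by Sibjeondaebo-tang and Glycyrrhizae (47 by chance), 96 by Palmul-tang and Glycyrrhizae (26) and 58 by Poria and Glycyrrhizae (15.8). Palmul-tang and Atractylodis shared 0 higher genes (0.258 by chance) and 5 lower genes (0.135; Fisher adjusted p = 2.1e-07). No chance number was computed for genes called in opposite directions, so those counts by themselves do not show opposed responses. The pairs do not share libraries. Over all 17764 genes the log2 changes of paired extracts correlated weakly, with Pearson from -0.0407 to 0.146 and Spearman from 0.0571 to 0.253. For Sibjeondaebo-tang and Palmul-tang these were 0.0788 and 0.229. The overlaps count only called genes, and sharing among the genes not called was not tested.

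The next question was how each extract at 500 µg/mL differed from the vehicle. The vehicle libraries carry a sample code of their own, and no set of extract libraries has its own vehicle, so an extract and a set difference cannot be told apart in these comparisons by themselves. The library labels name DMSO only for the vehicle, so a solvent difference cannot be told apart either. On principal component 3 (4.43% of variance) the 3 vehicle libraries lie between -30.7 and -23.7, and the other 57 lie between -14.5 and 17.8. The low doses already differed from the vehicle by 2743 to 5121 genes. Few high-dose calls against vehicle were also called against low dose in the same direction, except with Glycyrrhizae. These were 173 of 2693 (Sibjeondaebo-tang), 214 of 3938 (Palmul-tang), 141 of 2895 (Poria), 23 of 4639 (Atractylodis), 4766 of 8310 (Glycyrrhizae) and 101 of 5134 (Ginseng). Already called that way at low dose were 1955, 1872, 1855, 3253, 3280 and 3783. The first counts share the high-dose libraries and the second the vehicle libraries between comparisons, which by itself favours calls in the same direction. A set difference alone would not give the 4766, as both Glycyrrhizae doses share a set code.

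Dose calls often ran against the low-dose difference from the vehicle. Of the genes called between high and low dose, those called in the opposite direction between low dose and vehicle numbered 390 of 672 for Sibjeondaebo-tang, 124 of 370 for Palmul-tang, 98 of 275 for Poria, 13 of 37 for Atractylodis, 1395 of 6568 for Glycyrrhizae and 108 of 214 for Ginseng, and those called in the same direction 10, 15, 14, 5, 1048 and 22. Both comparisons use the low-dose libraries, which by itself favours opposite calls. With Sibjeondaebo-tang 11 of 24 G2/M genes were lower than the vehicle at low dose and 11 were higher at high dose. INSIG1 stood at 52.8 to 54.7 CPM at low and 61.5 to 67.8 CPM at high Poria dose, and at 51.1 to 54.8 and 64.6 to 66.6 CPM with Ginseng, against 75.8 to 76.1 CPM in the vehicle libraries, so its rise with dose did not reach the vehicle level.

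Glycyrrhizae at high dose against vehicle gave 4132 genes higher and 4178 lower, 521 and 422 of them at least 2-fold. The ATF4 list (25 of 27 higher), the aryl hydrocarbon receptor list (8 of 11 higher) and amino acid transport (11 of 12 higher) led, with CYP1A1 (9.38 ± 0.18), CYP1B1 (2.98 ± 0.04), ASNS (2.90 ± 0.05) and ULBP1 (5.03 ± 0.32). MAP kinase output (13 of 20) and p53 targets (13 of 22) were higher. G1/S genes (19 of 24), G2/M genes (18 of 24), coagulation and complement (12 of 16), glucocorticoid targets (10 of 16) and hepatocyte markers (5 of 6) were lower, with MAPK4 (-3.32 ± 0.12), LEFTY1 (-3.24 ± 0.16) and the surfactant protein SFTPD (-2.23 ± 0.12). These 10 lists held with an estimated correlation, but cholesterol synthesis (13 of 25 lower, adjusted p = 0.0958 with an estimated correlation), respiratory chain (0.15), heat shock (0.143), PPAR targets (0.141) and NF-kB cytokines (0.141) did not. At medium dose 2880 genes were higher and 2962 lower, and at low dose 2597 and 2522; when only the 6 libraries were fitted, the medium-dose total of 5842 became 3637.

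Sibjeondaebo-tang at high dose against vehicle gave 1606 genes higher and 1087 lower. The acute-phase gene SAA2 (1.42 ± 0.09), the complement gene CFB (1.04 ± 0.10) and the chemokine CXCL8 (1.63 ± 0.14) were higher, as were 9 of 24 NF-kB cytokine genes (10 adjusted over the list alone). G2/M genes (11 of 24), heat-shock genes (8 of 15) and aryl hydrocarbon receptor targets (2 of 11, with CYP1B1 (0.46 ± 0.04)) were higher, cholesterol synthesis genes (7 of 25) were lower, and ID2 (-0.96 ± 0.09) and ID3 (-0.74 ± 0.07) fell. These 5 lists held with an estimated correlation. Ribosomal protein genes fell in 11 of 24 (adjusted p = 0.164 with an estimated correlation). The high-dose total of 2693 became 1514 when only the 6 libraries were fitted and 1629 without vehicle replicate 2. At medium dose 1820 genes were higher and 1455 lower, together 3275, or 1962 without vehicle replicate 2, and at low dose 2240 and 2042.

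Palmul-tang at high dose against vehicle gave 2159 genes higher and 1779 lower. CXCL8 (1.71 ± 0.15), SAA2 (26 ± 1.03 against 10.6 ± 0.54 CPM, mean ± SD), CFB (1.00 ± 0.10) and CYP1B1 (0.58 ± 0.04) rose and ID2 (-1.13 ± 0.11), ID3 (-0.87 ± 0.08) and the small heat-shock protein CRYAB (-0.96 ± 0.20) fell. G2/M genes (16 of 24), NF-kB cytokines (9 of 24) and aryl hydrocarbon receptor targets (4 of 11) were higher and held with an estimated correlation, whereas ribosomal protein genes fell in 14 of 24 (adjusted p = 0.133 with an estimated correlation). The high-dose total of 3938 became 2547 without high-dose replicate 2 and 1977 without high-dose replicate 3. The medium dose gave 2001 higher and 1587 lower, together 3588, or 1210 without medium-dose replicate 3. The low dose gave 1550 and 1193, together 2743, or 1703 without vehicle replicate 2, 1646 without low-dose replicate 2 and 822 without low-dose replicate 3.

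Poria at high dose against vehicle gave 1756 genes higher and 1139 lower. G2/M (20 of 24), G1/S (12 of 24), fatty acid synthesis (7 of 13), amino acid transport (6 of 12), heat shock (7 of 15) and aryl hydrocarbon receptor targets (2 of 11) were higher and held with an estimated correlation. CYP1B1 (0.37 ± 0.04) and HMOX1 (0.33 ± 0.08) rose and ID2 (-0.86 ± 0.09) and DKK1 (-0.58 ± 0.07) fell, while ribosomal protein genes fell in 11 of 24 (adjusted p = 0.143 with an estimated correlation). The high-dose total of 2895 became 1906 without vehicle replicate 2. The medium dose gave 2200 and 1633, together 3833, or 2544 without medium-dose replicate 3. The low dose gave 1936 and 1536, together 3472, or 2138 without vehicle replicate 2, 2212 without low-dose replicate 1 and 2988 without low-dose replicate 3.

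Atractylodis at high dose against vehicle gave 2454 genes higher and 2185 lower. Cholesterol synthesis genes fell in 19 of 25 (20 adjusted over the list alone) with INSIG1 (-0.62 ± 0.04) and MVD (-0.57 ± 0.07), and NF-kB cytokine genes fell in 12 of 24 and rose in 2, with SAA2 (-1.02 ± 0.11) and CXCL1 (-0.85 ± 0.11) lower. Both lists held with an estimated correlation. INSIG1 already stood at 52.2 to 55.4 CPM at low Atractylodis dose, against 75.8 to 76.1 CPM in the vehicle. SAA2 stood at 4.99 to 7.41 CPM at low Atractylodis dose, against 10.1 to 11.1 CPM in the vehicle. At every dose SAA2 was also below the vehicle range with Glycyrrhizae, Ginseng, Angelicae and Paeoniae, and above it with Sibjeondaebo-tang and Palmul-tang. Much of these gaps to the vehicle is thus present at low dose. Hypoxia and glycolysis genes rose in 10 of 22 (adjusted p = 0.223 with an estimated correlation), ribosomal protein genes fell in 19 of 24 (0.133) and respiratory chain genes fell in 14 of 24 (0.451). The medium dose gave 2076 and 1790, together 3866, or 2547 without vehicle replicate 2, and the low dose 2254 and 1955.

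Ginseng at high dose against vehicle gave 2698 genes higher and 2436 lower. The nuclear RNA MALAT1 (1.13 ± 0.09), the ciliary transcription factor RFX3 (1.06 ± 0.11) and ALDOC (0.82 ± 0.10) rose, and PDZK1IP1 (-0.76 ± 0.08) fell. SULT1A4 (-0.71) was called lower but shares reads with a near-identical copy. Ribosomal protein genes fell in 16 of 24 (adjusted p = 0.355 with an estimated correlation), hypoxia and glycolysis genes rose in 12 of 22 (0.355), respiratory chain genes fell in 9 of 24 (0.411) and LXR targets fell in 4 of 9 (0.355) and cholesterol synthesis genes rose in 12 of 25 and fell in 4 (0.411), and none of these lists held. The medium dose gave 2672 and 2595 and the low dose 2600 and 2521, and when only the 6 libraries were fitted the low-dose total of 5121 became 3211. RFX3 was also among the largest rises of genes at 5 CPM or more against the vehicle for 4 other extracts. These rises were 0.96 for Sibjeondaebo-tang, 1.01 for Palmul-tang, 0.98 for Poria and 1.07 for Atractylodis. All these comparisons share the same vehicle libraries, so the RFX3 rises are not independent and do not by themselves show a recurring response. Of the 5134 Ginseng calls, 3783 were already called that way at low dose, and 101 were also called against low dose.

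**Figure D3:**
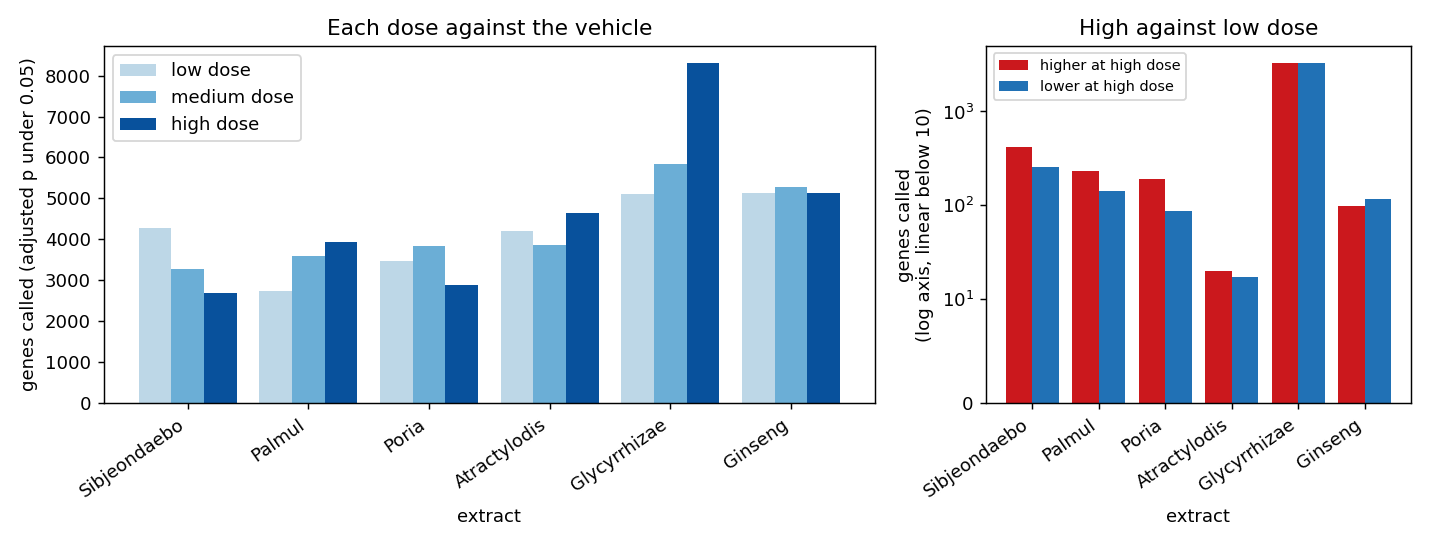
Bars show genes called at adjusted p under 0.05 for each dose against the vehicle (left) and for high against low dose (right, log axis, linear below 10) in 6 extracts. Glycyrrhizae has 3295 genes higher and 3273 lower at high dose than at low dose, and Atractylodis 20 and 17.

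**Figure D4:**
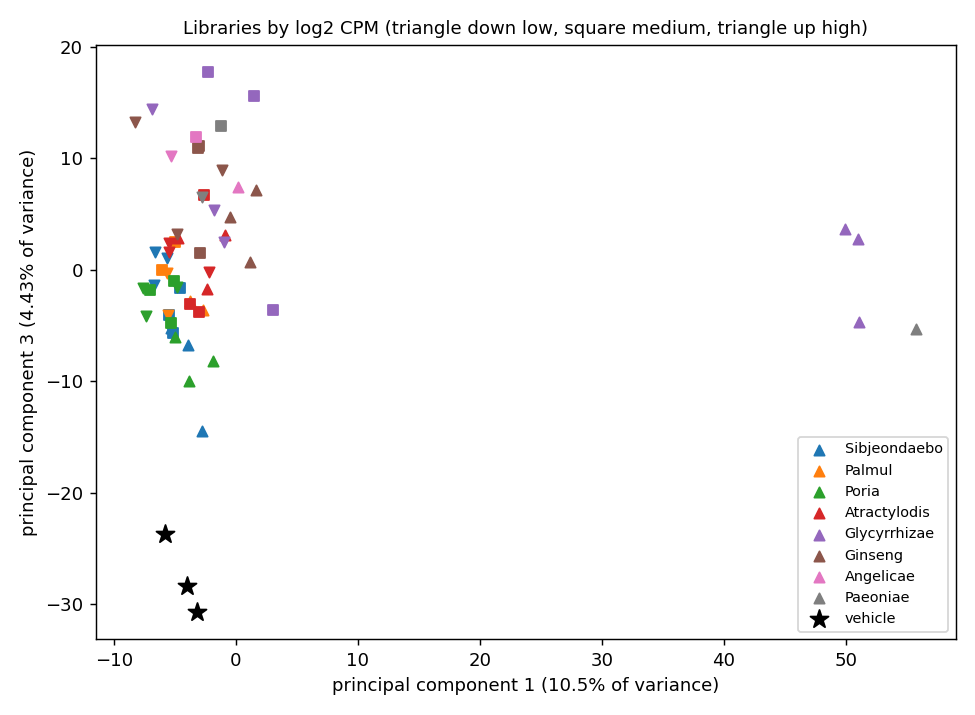
Principal components 1 (10.5% of variance) and 3 (4.43%) of log2 CPM, with 1 point per library, colours for extracts and symbol shapes for doses. The high-dose Glycyrrhizae libraries lie at 49.95 to 51.05 on component 1 and the high-dose Paeoniae library at 55.8. Component 2 (5.985% of variance), not drawn, sets them apart, at 23.71 to 25.73 for Glycyrrhizae and -67.11 for Paeoniae.

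Extracts that share a set of sample codes were then compared at high dose, to ask which genes tell them apart. Glycyrrhizae against Ginseng gave 2954 genes higher and 3149 lower. CYP1A1 (9.82 ± 0.18), CYP1B1 (2.75 ± 0.04), ADM2 (4.48 ± 0.20), ASNS (2.65 ± 0.05) and DDIT3 (2.17 ± 0.09) were higher with Glycyrrhizae, and CLDN2 (-3.81 ± 0.30), the synaptic gene CPLX2 (-2.16 ± 0.04) and the cholesterol enzyme HMGCS1 (-1.01 ± 0.05) were lower. CYP1A1 stood at 215 ± 5.34 against 0.237 ± 0.106 CPM (mean ± SD, n = 3 and 3; edgeR adjusted p = 1.23e-37).

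Poria against Atractylodis gave 329 genes higher and 196 lower at high dose. SAA2 (0.82 ± 0.11, edgeR adjusted p = 3.9e-06; 9.2 ± 0.281 against 5.2 ± 0.572 CPM, mean ± SD, n = 3 and 3), CXCL1 (0.68 ± 0.11) and HMGCS1 (0.45 ± 0.05) were higher with Poria. TF (-0.68 ± 0.10), the vitamin D hydroxylase CYP24A1 (-0.60 ± 0.07) and ID2 (-0.59 ± 0.09) were lower. The 525 calls became 218, 320 and 344 without Poria high-dose replicates 1, 2 and 3, and 214 and 291 without Atractylodis high-dose replicates 2 and 3.

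Sibjeondaebo-tang against Palmul-tang gave 0 genes at high dose by edgeR and 0 by DESeq2, and 102 were called with no filter on low counts. In edgeR 1096 of 17764 genes were at unadjusted p under 0.05, where a share of 0.05 is expected with no difference. CYP1B1 differed by -0.12 ± 0.04 (edgeR adjusted p = 0.723; 154 ± 2.69 against 167 ± 0.984 CPM, mean ± SD, n = 3 and 2) and CXCL8 by -0.08 ± 0.13, so neither the metabolic nor the inflammatory gene was told apart with these samples.

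Angelicae and Paeoniae have 1 library per dose, so genes are described without a test, and counts are of changes of at least 2-fold that lie outside the vehicle range. Paeoniae at high dose had 275 genes higher and 279 lower, against 4, 3 and 2 genes when each vehicle library was set against the other 2. IGFBP3, a carrier of insulin-like growth factors, stood at 84.9 CPM against 4.33 ± 1.22 CPM in the vehicle (mean ± SD, n = 3; log2 4.01). The calcium-regulating hormone STC1 (2.84), NDRG1 (2.75) and the glycolytic genes ALDOC (2.53) and HK2 (2.52) followed, and the hypoxia and glycolysis list had a median of 1.83. Median changes were 0.76 for ATF4 targets, 0.75 for p53 targets, 0.84 for MAP kinase output, -0.57 for heat-shock genes, -0.48 for G2/M and -0.43 for G1/S genes. Lower genes were the serine dehydratase SDS (-2.37), PAQR6 (-2.32) and HAPLN3 (-2.10), and BOLA2 (-3.11), which shares reads with a near-identical copy.

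At low and medium dose Paeoniae had 19 and 2 such genes, where the medium-dose count was 5 without vehicle replicate 3. Mitochondrial genes held 25.9% of counts in the low-dose and 24.3% in the high-dose Paeoniae library, the 2 highest shares of the 60 libraries (15.9 to 19.1% in the vehicle), and the median change of the list encoded by mitochondrial DNA was 0.72 and 0.51; the cause was not tested. Angelicae had 4, 3 and 3 genes from low to high dose, close to the vehicle's own 4, 3 and 2. ZNG1F, which has near-identical copies, stood at 24.2 CPM at high Angelicae dose against 5.935 ± 0.797 CPM in the vehicle. The other Angelicae genes named here stayed under 2-fold. With Angelicae CYP1B1 stood at 129.5, 146.3 and 184.6 CPM and the cystine transporter SLC7A11 at 143.2, 147.7 and 160.2 CPM from low to high dose, against 112.3 ± 0.672 and 96.8 ± 3.18 CPM in the vehicle. The sterol-regulated gene INSIG1 stood at 49.6, 49.1 and 38.4 CPM against 75.9 ± 0.144 CPM and MVD at 39.2, 38.4 and 30.3 against 52.6 ± 5.18 CPM, and the cholesterol synthesis list had a median of -0.27 at high dose. The low-dose libraries of the other 7 extracts had INSIG1 at 51.1 to 55.4 CPM, and mean SLC7A11 at low dose was 126.1 CPM with Sibjeondaebo-tang and Atractylodis, 131.2 with Ginseng and 134.7 with Glycyrrhizae, so much of these gaps to the vehicle is not particular to Angelicae.

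Markers of other cell types were checked in every high-dose comparison. Of 8 fibroblast markers tested by edgeR, none rose or fell between high and low dose with Sibjeondaebo-tang, Poria, Atractylodis and Ginseng, 1 fell with Palmul-tang, and 1 rose and 3 fell with Glycyrrhizae; camera adjusted p of the list was 0.361, 0.121, 0.197, 0.848, 0.406 and 0.496 in that order. Against the vehicle at high dose 1 rose and 1 fell with each of Glycyrrhizae and Ginseng and none with the others, with camera adjusted p of at least 0.397. Only 2 leukocyte and 3 endothelial markers passed the count filter, too few for a list test.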

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

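The tests in this part, of the difference between 2 extracts in the change from low to high dose, were not in the plan fixed before the data were examined. They were added later, for all 3 pairs of extracts within a set of sample codes. Between Sibjeondaebo-tang and Palmul-tang 0 genes were called by edgeR. At unadjusted p under 0.05 were 904 of 17764 genes, close to the share of 0.05 expected with no difference.

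The change from low to high dose differed between Poria and Atractylodis for 13 genes (10 higher, 3 lower in Poria; 1293 at unadjusted p under 0.05) by an interaction test in edgeR. The differences in log2 change, Poria minus Atractylodis, were -0.57 for CYP24A1, which inactivates vitamin D, -0.46 for MATN2, a matrix protein, and -0.39 for ID1, a helix-loop-helix inhibitor. They were 0.44 for GTSE1, a G2/M gene, 0.39 for HMGCS1 and 0.38 for INSIG1, both of sterol synthesis. MATN2 and ID1 were chosen after their values were seen.

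The change differed between Glycyrrhizae and Ginseng for 3738 genes (1727 higher and 2011 lower in Glycyrrhizae). The differences, Glycyrrhizae minus Ginseng, were 8.70 for CYP1A1, 2.50 for CYP1B1, 5.14 for ULBP1 and 4.64 for ADM2. CYP1A1 had 16, 6 and 16 counts at low Glycyrrhizae dose and 2 to 8 in the Ginseng libraries at low and high dose, and ULBP1 had 11, 9 and 4 at low Glycyrrhizae dose, so these 2 differences rest on few counts on one side. KLHL30 (5.40), FUT1 (5.40) and IL1A (4.25) were chosen after their values were seen and rest on few counts. KLHL30 had 0, 0 and 0 counts at low Glycyrrhizae dose and 3, 10 and 7 at high dose, so its fitted difference depends on the prior count and is no bound. The vehicle libraries held 3, 4 and 4 KLHL30 counts. FUT1 had 9, 3 and 3 counts against 114, 101 and 123, and IL1A had 0, 1 and 3 against 31, 26 and 31.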

How the results depend on the processing

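The replicate block within set codes, the length and GC correction and the thinning to one depth were chosen after the results were seen. RLE size factors left every count of called genes within 1.5 times. For single named genes the direction never turned under any alternative run, and calls were lost only with no low-count filter, in fits of only the compared libraries or without 1 library. This covers only results that had an adjusted p in the alternative run. There were 141 of them with DESeq2 and 142 in fits of only the compared libraries, against 144 with RLE size factors. Fitting only the compared libraries gave 1514 genes for Sibjeondaebo-tang high, 3637 for Glycyrrhizae medium and 3211 for Ginseng low against vehicle, and for high against low dose 323 (Sibjeondaebo-tang), 577 (Palmul-tang), 123 (Poria), 21 (Atractylodis) and 21 (Ginseng). These fits hold fewer samples and use only the spread of the compared groups, while the main fit shares its spread estimate over all groups. The spread was unequal: chi-square per degree of freedom was 40.3 for Ginseng low-dose replicates 2 and 3 and 2.72 for the Palmul-tang low-dose pair. The shared estimate may thus be too small for some comparisons and too large for others. DESeq2 called 67 and no low-count filter 209 for Atractylodis high against low dose, and no filter 102 for Sibjeondaebo-tang against Palmul-tang; the cause was not tested. Replicate numbers were not taken to pair the samples, because correlations of residuals with the same number ran from -0.0994 to 0.104, although every sample correlated best with its own number in 5 of the comparisons with 3 pairs (high against low dose for Poria and Ginseng, Ginseng medium against vehicle, Poria against Atractylodis, Glycyrrhizae against Ginseng) and in 3 of those with 2 pairs (Palmul-tang high and medium against vehicle, Sibjeondaebo-tang against Palmul-tang). The share of counts in long noncoding and intronic gene types was 1.27 to 1.37% in replicate 1 of Sibjeondaebo-tang. It was 0.957 to 1.11% in replicates 2 and 3 of that set of sample codes. In replicate 3 of Poria and Atractylodis it was 1.303 to 1.489%, against 0.987 to 1.15% in replicates 1 and 2. Libraries of these sets thus share a trait by replicate number, which the main fit does not model. Palmul-tang has no replicate 1, so its comparison with Sibjeondaebo-tang is unbalanced in that trait. Whether shared handling is the cause was not tested. A replicate block gave 66 genes for Atractylodis high against low dose and 10 list calls for Palmul-tang; within set codes it gave 1014 (Sibjeondaebo-tang), 577 (Palmul-tang), 493 (Poria), 86 (Atractylodis) and 334 (Ginseng), and 2 for Sibjeondaebo-tang against Palmul-tang and 850 for Poria against Atractylodis; the cause was not tested. With an estimated correlation, lists called against vehicle numbered 5 (Sibjeondaebo-tang), 3 (Palmul-tang), 2 (Atractylodis) and 0 (Ginseng; camera, by the preset correlation 5), and high against low dose 6 (Sibjeondaebo-tang), 8 (Atractylodis) and 8 (Glycyrrhizae). Genes shared with Atractylodis by Sibjeondaebo-tang, Palmul-tang, Poria, Glycyrrhizae and Ginseng numbered 25, 14, 24, 54 and 31 by DESeq2 and 23, 12, 21, 49 and 30 with the block. Without a CPM minimum the unreplicated extracts had 24, 20 and 17 (Angelicae) and 49, 17 and 850 genes (Paeoniae), low to high. Between the mean of the low doses and the vehicle 3052 genes were called after a length and GC correction and 6045 without it, 2120 of them both ways in the same direction. Leaving out 1 library gave these ranges of called genes, against vehicle (high, medium, low): Sibjeondaebo-tang 1629 to 2547, 1962 to 3222, 2908 to 4041, then Palmul-tang 1977 to 3828, 1210 to 3661, 822 to 2801, then Poria 1906 to 2890, 2544 to 3728, 2138 to 3425, then Atractylodis 3392 to 4388, 2547 to 3729, 2846 to 3981, then Glycyrrhizae 7425 to 7807, 4559 to 6134, 3946 to 4866, then Ginseng 4005 to 4866, 3940 to 5070, 3968 to 4871. For high against low dose: Sibjeondaebo-tang 381 to 503, Palmul-tang 106 to 169, Poria 144 to 192, Atractylodis 13 to 31, Glycyrrhizae 5774 to 5940, Ginseng 92 to 245. Between extracts: Sibjeondaebo-tang against Palmul-tang 0 to 0, Poria against Atractylodis 214 to 407, Glycyrrhizae against Ginseng 5320 to 5502. For the unreplicated extracts (low, medium, high): Angelicae 3 to 5, 3 to 4, 3 to 4, Paeoniae 14 to 24, 3 to 5, 553 to 563. With 18602484 to 29764358 counts per library, depth limits what can be said of genes with few counts, such as CYP1A1 at under 1 CPM; this limit was not compared with the spread between replicates.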

Other observations

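The dose test and the batch count for the vehicle libraries and all 3 tests of the Poria library were chosen only after the result was seen.

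Several dose responses recurred across extracts. ID2 fell between low and high dose with Sibjeondaebo-tang (-0.59) and Palmul-tang (-0.82), and the Wnt antagonist DKK1 fell with Palmul-tang (-0.66) and Poria (-0.42). The Nodal antagonist LEFTY1 fell with Ginseng (-0.75) and Glycyrrhizae (-3.34).

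The mean of the 17 low-dose libraries of the tested extracts differed from the vehicle by 6050 genes (3006 higher, 3044 lower). Thinning every library to the smallest total gave 5706 calls, 94.3% as many (93.9 to 94.6% without 1 vehicle library), of which 5507 were among the 6050 in the same direction, which argues against lower depth of the vehicle libraries. A correction of each library for transcript length and GC gave 50.5% as many calls (36.8 to 49.4% without 1 vehicle library), 2120 of them called both ways in the same direction, so such a bias may make part of the pattern. The genes moved back towards the vehicle at high dose in 4 of 6 extracts (3 with each library left out), so a response to the extracts that grows with dose is neither shown nor excluded. A separate handling batch cannot be told apart from the vehicle group, because 0 set codes hold both vehicle and extract libraries. A solvent difference was not tested, as the library labels name DMSO only for the vehicle. The submitters' titles carry the same batch label for all 60 libraries, and what that label covers is not stated.

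Poria low-dose replicate 3 had 27941 genes above 0 after rounding, against at most 23424 elsewhere, and its 3495 extra genes held 5009 counts, 0.0208% of the library. The 10 most abundant held 2.02% of those counts, which argues against RNA from another cell type or library, and its total of 24061989 counts lies within the range of the others (18602484 to 29764358), which argues against greater depth. Over 4059 nearly silent protein-coding genes, counts went with transcript length at Spearman rho 0.477 in this library, across genes, which are not independent replicates (0.0478 to 0.123 in the others). These genes were chosen for a mean count under 0.5 in the other libraries. There at most 382 were above 0, against 1663 here, which by itself lowers rho in the others. Counts from RNA can also go with transcript length, so rho does not tell genomic DNA from RNA. Reads spread over the genome, such as genomic DNA, are a candidate explanation for these extra genes. No biological explanation was tested.

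Each comparison of 3 libraries with 3 was refitted on its 6 libraries under all 10 splits, and the real split alone gave the highest count (1 of 10 in each). With 10 splits the share is never under 0.1. The real and the highest other counts follow. For Sibjeondaebo-tang they were 1514 and 3 (high dose against vehicle), 3155 and 2 (medium dose against vehicle), 3976 and 0 (low dose against vehicle) and 323 and 6 (high against low dose). For Poria they were 2911 and 1 (high dose against vehicle), 3621 and 2 (medium dose against vehicle), 2346 and 1 (low dose against vehicle) and 123 and 3 (high against low dose). For Atractylodis they were 4243 and 1 (high dose against vehicle), 2668 and 1 (medium dose against vehicle), 3579 and 2 (low dose against vehicle) and 21 and 2 (high against low dose). For Glycyrrhizae they were 7767 and 0 (high dose against vehicle), 3637 and 1 (medium dose against vehicle), 3943 and 1 (low dose against vehicle) and 5838 and 0 (high against low dose). For Ginseng they were 4836 and 0 (high dose against vehicle), 4984 and 2 (medium dose against vehicle), 3211 and 2 (low dose against vehicle) and 21 and 1 (high against low dose). For the extracts compared at high dose they were 539 and 3 (Poria against Atractylodis) and 6105 and 0 (Glycyrrhizae against Ginseng).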
